A study of Homo sapiens with 10 samples.

How the data were processed

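The study followed 2 human colorectal cancer cell lines, SW480 and LS174T, through successive passages as liver metastases in immunodeficient mice. Each line has a parental stage and the derivatives LvM1 and LvM2, taken from the earlier and the later passage. ATAC-seq, which cuts open chromatin with a transposase, was analysed here for 6 bulk libraries, 1 library per line and stage. There were no replicates, so no test between stages and no spread within a stage was computed. The study's other 4 samples, 2 of scRNA-seq and 2 of SW480 scATAC-seq, were not analysed here, because every comparison was built on a peak list per bulk library.

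Per the submitters' processing notes, the tools were Trim Galore 0.6.4, FastQC 0.11.9, Bowtie2 2.4.1 and MACS2 2.2.6, with the genome build hg38 (GRCh38). The notes give the same tools for every sample and state neither their order nor their settings. Each deposited peak carries a display score, which in these lists is the whole part of the authors' -log10 q multiplied by a constant. It carries the authors' fold enrichment, a ratio of the summit to the local background that was not scaled between libraries. The deposited lists also give the authors' -log10 p and -log10 q of each summit, and the lowest -log10 q of every list corresponded to a q of 0.05. These peak values are the authors' own and were used only to describe, rank or filter peaks within a list.

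Peaks on the 22 autosomes and chromosome X were used, and peaks on other sequences were left out because the gene table was limited to the same chromosomes. No filter for repeats or regions of extreme signal was applied here. The lists of a line were joined into 1 set of regions wherever peaks overlapped. A region was called gained when it had a peak in both LvM lists and none in the parental list, and lost when it had a peak in the parental list alone. For a region closed in every stage, a chance peak in a single list can give a loss but no gain. For one open in every stage, a peak missed in a single list can give a gain but no loss. The counts of gained and lost regions are therefore not even by construction. Kept regions had a peak in all 3 lists. The RefSeq gene table of GRCh38.p14 held the ends of 19974 protein-coding genes but neither strand nor transcript starts. A gene was therefore given a peak when a peak came within 1000 bp of either annotated end, in place of the promoter windows planned before the data were examined. Gene ends here include 3' ends and any neighbouring gene's promoter. No genome sequence was at hand, so the planned motif counts were not run.

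The number of reads covering each summit, called the pileup below, and the local background were recovered from the authors' fold enrichment and -log10 p. Every peak of the 6 lists gave exactly 1 whole pileup that returned its -log10 p within 0.0005. The recovery was tested on 10000 simulated peaks and returned 100% of their pileups. The genome background behind the lists was 0.757, 0.763 and 0.660 reads for SW480 parental, LvM1 and LvM2, and 13.1, 13.7 and 15.5 reads for LS174T. The LS174T libraries were 17.2 to 23.5 times as deep by this measure. Median summit pileups were 14 to 15 reads in SW480 and 38 to 42 in LS174T, so that many SW480 peaks rested on few reads.

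Shares of peaks are given with exact Clopper-Pearson intervals at 95%, which cover counting error only. For 23 gene lists, 5 of them markers of other cell types, gained and lost members were counted. Each count was placed among 10000 random lists of the same size, matched on how many of the other line's libraries had a peak at the gene. These percentiles describe these libraries and are no test of the stages. A percentile of 97.5 or more is called high below. Ties were placed at their middle rank, so a count can be high although over 2.5% of random lists reached it. Genes gained or lost in both lines were compared with the number for independent lists, with an exact hypergeometric interval. Peaks of equal rank were compared by taking as many peaks as 25% of the shortest list of a line, best by -log10 q, from each of its lists. They were looked up in the full lists, which differ in length, so that rank was matched but not strength. Overlap in bases was computed as a Jaccard index for all 15 pairs of libraries.

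The genes to be named were fixed by rule. For each line and direction these were the 10 genes whose peak ranked best by -log10 q in its own list. For gained genes the worse of the LvM1 and LvM2 ranks counted. Every gained or lost member of a gene list was also named, or the 4 of best rank where a list had more than 8. Added to these were HMG20B, the gene in the study's title, the 10 best-ranked genes gained or lost in both lines, and the 3 best-ranked regions per line and direction away from gene ends. Of the genes under this rule, 1 gained in LS174T is left unnamed. Named beyond the rule are the remaining gained HOX genes of SW480, genes that changed in opposite directions, and examples from kept regions. The gene lists, this rule, the comparisons and the alternatives of the next paragraph, apart from the last 3, were set before the data were examined.

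The alternatives set in advance were peaks with -log10 q of at least 5, lists cut to equal length, an overlap of 50% of the shorter interval, and summits widened by 250 bp. Further ones were windows of 250 bp, each LvM library on its own against the parental list, unmatched random lists, the best 10% of peaks, and ranking by fold enrichment. A further 3 kinds of alternative were chosen after seeing the data. The first asked whether the pileup of a gained or lost region, scaled by the median ratio in kept regions, would still be called in the library that lacked it, with a risk of under 0.001 of missing it. In simulated data this rule kept 0 of 1987 unchanged regions, and 35 of 200 truly absent ones, among them 100% of the 12 with a mean pileup of at least 40. The absent regions were absent from the parental library only. Lost regions were not simulated, so the rule has no known error rate for them. The second counted a gene end as occupied wherever any part of the joined region was present, since a wider peak can reach into a window that a narrower one misses. The third used only gene ends with no end of another gene within 5 kb.

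Pileup changes in kept regions were also chosen after seeing the data. They are log2 ratios of LvM to parental pileup, centred on the median of kept gene ends in the same of 20 bins of total pileup, or on the median of all kept regions for chromosomes. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots matplotlib 3.10.9. Overlaps were checked against a comparison of every pair of 1500 simulated intervals.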

Results

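Open chromatin in SW480 and LS174T, both lines derived from human colorectal carcinomas, was compared between parental cells and the liver-passaged derivatives LvM1 and LvM2. In SW480, peaks were deposited at 16448 positions in parental cells, 28794 in LvM1 and 22733 in LvM2. Of the SW480 peaks on the chromosomes compared, 42.3% lay at gene ends in parental cells, 34.5% in LvM1 and 38.8% (95% interval 38.2 to 39.4%) in LvM2. LS174T had 203917, 245011 and 227983 peaks, and 7.49%, 6.93% and 6.79% of them lay at gene ends. Peaks covered 6.36, 13.6 and 10.9 Mb in SW480, and 85.3, 91.4 and 88.2 Mb in LS174T. Of 19974 protein-coding genes, 7831, 10738 and 9791 had a peak at an end in SW480, and 13762, 14495 and 13582 in LS174T. The list lengths of the lines are not comparable, since the LS174T libraries were far deeper.

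HMG20B, a DNA-bending protein of the LSD1-CoREST repressor complex, had a peak at 1 end in all 6 libraries. The gene lies on chromosome 19 from 3572944 to 3579083, and the peak lay at its lower end, from 3572635 to 3572973 in SW480 parental cells. Its summit pileup in SW480 was 16 reads (95% Poisson interval 9.15 to 26.0) in parental cells, 38 (26.9 to 52.2) in LvM1 and 44 (32.0 to 59.1) in LvM2. In LS174T it was 235 (206 to 267), 269 (238 to 303) and 170 (145 to 198) reads. The authors' fold enrichment at this HMG20B peak was 4.68, 8.15 and 9.19 in the SW480 lists and 5.72, 6.31 and 4.30 in the LS174T lists. The Poisson intervals cover counting error only and no spread between libraries of a stage. These pileups were not scaled for depth, and the median ratio of LvM to parental pileup in kept regions of SW480 was 1.53 in LvM1 and 1.35 in LvM2. In LS174T it was 1.04 and 1.07. Kept gene ends of LS174T LvM2 lay below the median of all kept regions on every autosome. Their median log2 difference ran from -0.32 on chromosome 18 to -0.26 on chromosome 13, against -0.05 to 0.07 elsewhere. Relative to kept gene ends of similar pileup, HMG20B was at -0.21 in LS174T LvM2.

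Among SW480 genes with a peak in both LvM lists and none in parental cells were NDST1, an enzyme of heparan sulfate synthesis, and RNF181, a ubiquitin ligase. RNF181 had 48 reads in LvM1 and 37 in LvM2, and NDST1 had 37 and 41. TMEM191C, a transmembrane protein gene on chromosome 22, had 32 and 28 reads. In all, 2008 genes were gained in SW480 and 168 were lost. Gained regions numbered 5362, of which 35.2% (33.9 to 36.5%) lay at gene ends, against 10.1% (8.95 to 11.2%) of the 2766 lost regions and 53.6% of the 11235 kept ones. Away from gene ends, the best-ranked gained regions lay within VRK3, a kinase-like gene, on chromosome 19 from 49987198 to 49987636, and within ABCA7, a lipid transporter gene, from 1045121 to 1045563. The other lay on chromosome 5 from 142342196 to 142342964, nearest to SPRY4, an inhibitor of receptor tyrosine kinase signalling.

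The other 7 of the 10 best-ranked gained SW480 genes were PLAUR, KAT6B, HNRNPUL1, MAP3K11, KLHL12, CTDSPL and FLT3LG. At each of them the region was present in parental cells as a narrower peak 12 to 284 bp beyond the window of 1000 bp. PLAUR, the urokinase receptor, had 60 reads in parental cells, 70 bp beyond the window, and 111 and 130 in LvM1 and LvM2. TMEM191C and RNF181 were 2 of only 3 gained SW480 genes that passed the scaled calling limit. By that limit 10 of the 5362 gained and 233 of the 2766 lost regions remained, but in simulated data the limit kept 35 of 200 truly absent regions, among them all 12 with a mean pileup of at least 40. Simulated losses were not tried. Scaling by the median ratios of 1.53 and 1.35 lowers the expected pileup of every gained region and raises that of every lost one. The balance that the limit leaves thus does not bear on the full lists. With lists cut to equal length the balance turned, with 2676 regions gained and 4020 lost, under a rule that is not even for gains and losses.

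SW480 genes with a peak in parental cells alone included IL23A, a subunit of the cytokine interleukin-23, with 22 reads, and LRP5, a Wnt co-receptor, with 20. MRGPRG, a G protein-coupled receptor gene, had 24 reads, and ETFB, a mitochondrial electron transfer protein, had 29. CBLC, a ubiquitin ligase of epithelial cells, had 17 reads, PPCDC, an enzyme of coenzyme A synthesis, 18, and GPRIN1 19. KCNH8, a potassium channel gene, and BEST4, a channel gene that marks a subset of colonic enterocytes, had 15 reads each. These 9 genes passed the scaled calling limit, which was not tried on simulated losses. RAB34, a small GTPase gene and the best-ranked of the 10, did not pass the limit, and its whole region was present after passage. The best-ranked lost regions away from gene ends lay within HIPK2, a stress-responsive kinase gene, on chromosome 7 from 139732264 to 139732443, and on chromosome 17 from 36825738 to 36826354 and from 23190267 to 23190498.

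**Figure D1:**
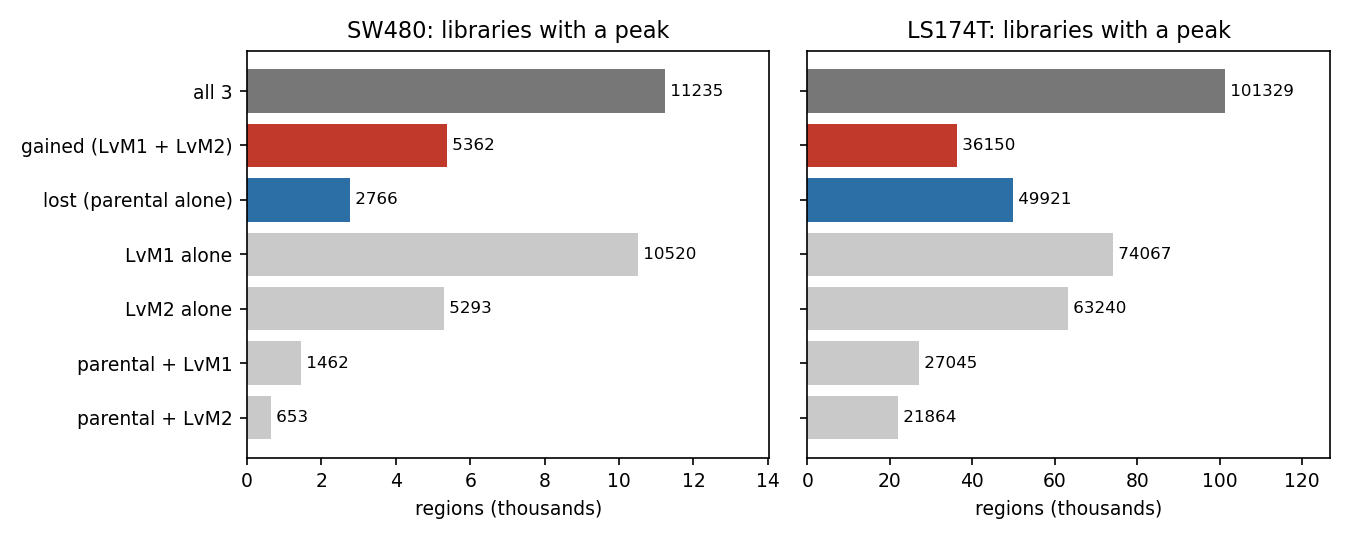
Number of regions (horizontal axis, in units of 1000) by which of the 3 libraries of a line had a peak there, for SW480 (left) and LS174T (right). Each bar is 1 pattern over the joined regions of the line. Gained regions outnumbered lost ones in SW480 (5362 and 2766), and lost regions outnumbered gained ones in LS174T (49921 and 36150). Gained asks for a peak in both LvM lists and lost for the parental list alone, so this balance is not even by construction. Regions with a peak in LvM1 alone or LvM2 alone numbered 10520 and 5293 in SW480, and 74067 and 63240 in LS174T.

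In LS174T, the genes with a peak in both LvM lists and none in parental cells included UBE2V1, a cofactor of ubiquitin chain assembly, with 175 reads in LvM1 and 135 in LvM2. SLC66A2 had 175 and 153 reads, and NAPB, a vesicle fusion factor, had 102 and 92. YIF1B, a membrane trafficking gene, had 202 and 167 reads and FAM24A had 130 and 109. CTU2, an enzyme of tRNA modification, and RNF166, a ubiquitin ligase, share 1 region of 167 and 144 reads on chromosome 16. The uncharacterised genes LOC102724159 and LOC102724200 likewise share a region of 183 and 125 reads on chromosome 21. All 10 best-ranked genes, 1 of them not named here, passed the scaled calling limit. The gained region of best -log10 q rank away from gene ends lay on chromosome 10 from 133689333 to 133689559, with 625 and 606 reads. The next ones lay on chromosome 16 from 46386371 to 46386570 and from 10877 to 11129. The former had 681 and 781 reads at fold enrichments of only 4.19 and 4.18, against 30.9 and 29.8 for the region on chromosome 10. Repeats and regions of extreme signal were not filtered out, so such peaks need not reflect open chromatin.

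LS174T genes with a peak in parental cells alone included MLST8, a subunit of the mTOR complexes, with 120 reads, and B4GALNT1, an enzyme of ganglioside synthesis, with 79. EMP3, a membrane protein gene, had 140 reads, and SNAP23, a membrane fusion protein, and ZNF106 share 1 region of 95 reads. These 5 passed the scaled calling limit, which was not tried on simulated losses. The limit used a ratio of 1.07 for every LvM2 region, although kept gene ends there had lower ratios. If lost gene ends shared that shift, the limit passed them too readily, which was not tested. At KLHL12, PIF1, TGFBR3L, CD52 and FOXR2, the other 5 of the 10 best-ranked, the whole region was also present after passage, for CD52 in LvM1 alone. Lost regions away from gene ends lay on chromosome 22 from 37592560 to 37592783, on chromosome 9 from 3732609 to 3732895 and on chromosome 14 from 49173894 to 49174109.

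LS174T gained 720 genes and lost 518, and gained 36150 regions and lost 49921. Gene ends held 3.45% (3.27 to 3.65%) of the gained regions, 3.01% (2.86 to 3.16%) of the lost and 11.6% of the 101329 kept ones. By the scaled limit 1749 gained and 866 lost regions remained. These turned the balance but are only those with pileups high enough for the limit, so they do not bear on the full lists. The balance of regions also turned with LvM1 alone (110217 gained, 71785 lost) and LvM2 alone (99390 and 76966). With a single LvM library the rule is even for gained and lost, but the parental list is the shortest. The balance of genes turned with -log10 q of at least 5 (358 gained, 517 lost), lists of equal length (586 and 623) and LvM2 alone (1219 and 1399). Whether the lower pileups at kept gene ends of LvM2 bear on this balance was not tested. Of the gained LS174T genes, 92.4% had the LvM1 and LvM2 peaks at the same end of the gene, against 98.9% in SW480. The peaks lay at different ends of 23 gained genes in SW480 and 55 in LS174T, among the named genes at SMUG1 in SW480 and at CD2, EPHB2, HOXC11, IFI44L, ORM1 and SLC26A3 in LS174T.

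Genes of mesenchymal transition, the programme by which epithelial cells loosen and migrate, stood out in SW480. Of 30 measured, 8 had a peak in parental cells, 16 in LvM1 and 18 in LvM2, and 7 were gained. They were SNAI1 and ZEB1, transcription factors that repress epithelial genes, the matrix genes SPARC, TNC and TGFBI, LOXL2, a collagen cross-linking enzyme, and PLAUR. SNAI1 had 23 and 14 reads in LvM1 and LvM2, ZEB1 15 and 11, and SPARC 21 and 20. Random matched lists held 2.57 gained genes on average, and the count lay at percentile 99.4, or at 97.9 with 6 genes when whole regions were counted, which leaves out PLAUR. With windows of 250 bp the percentile was 97.3, with LvM1 alone 96.0, and with ends far from other genes 82.2.

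HOX genes, which set position along the body axis, gave the highest percentile in SW480, with 9 of 39 gained against 3.10 in random lists (percentile 99.8). HOXC4, HOXC5 and HOXC6 share 1 peak of 23 reads in LvM1 and 17 in LvM2. HOXC13 had 14 and 23 reads, HOXA5 28 and 14, HOXA6 26 and 21, and HOXA10 25 and 20, and the others were HOXD1 and HOXD9. Neighbouring HOX genes are not independent counts. No more than 4 of the 39 had an end away from other genes, and 0 of these were gained. The percentile was 82.4 with -log10 q of at least 5, 89.9 with lists of equal length and 73.8 with windows of 250 bp.

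Other SW480 groups lay closer to their random lists. Genes of the CoREST and HMG20B complex had 4 gained of 21 (percentile 88.6): PHF21A, a CoREST subunit, DTNB, and the repressors GFI1 and SNAI1, with the whole GFI1 region already present in parental cells. Metabolic genes linked to liver colonisation had 4 gained of 28 (71.1): FASN and SCD, enzymes of fatty acid synthesis, their regulator SREBF1, and ACSL4. FASN had 29 and 38 reads in LvM1 and LvM2. In TGF-beta and BMP signalling 4 of 27 were gained (70.8), namely the ligands TGFB1 and BMP2, the receptor BMPR1A and the target ID3. Interferon response and antigen presentation had 4 of 32 (59.7), namely HLA-B, HLA-C, IRF9 and NLRC5, a regulator of HLA class I genes.

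Epithelial identity genes showed no high count of gains in SW480. The transcription factors KLF4, SOX9 and PDX1 were 3 gained of 30 (percentile 39.5), and KRT18 and OCLN, a tight junction protein, were 2 of 30 junction and keratin genes (21.2), with KRT19 lost. CCND1 and LEF1 were gained among 28 Wnt targets and stem cell genes (26.9), and BEST2 and GFI1 among 26 goblet and secretory genes (28.4). ISL1 and SYP were gained among 22 enteroendocrine genes (61.7). Of 26 enterocyte absorption genes 0 were gained (4.26) and CA4, a carbonic anhydrase, was lost.

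Of the remaining SW480 groups, YAP and TEAD targets had the only high count of losses, with 2 of 25 lost, CRIM1 and TEAD3, against 0.206 in random lists (percentile 99.1). That group also had ASAP1, PTPN14 and TEAD4 gained (56.9). With -log10 q of at least 5, and with ends far from other genes, none of its genes was lost. The percentile of its losses was 89.4 with LvM2 alone and 92.1 with windows of 250 bp, and that of its gains 98.5 with -log10 q of at least 5. CYP2S1, CYP3A5 and GSTP1 were gained among 27 detoxification genes (56.4), and ERO1A and HK2 among 26 hypoxia genes (25.7). NFKB1 was gained and CXCL1, a neutrophil chemokine with 11 reads in parental cells, was lost among 24 inflammatory genes. CHMP2A, HPRT1 and RPS3 were gained among 30 broadly used genes (33.5), and 0 of 29 cancer-testis genes (13.7). Markers of hepatocytes and of immune cells had 0 gained (4.47 each) and those of fibroblasts 0 (11.0). CLDN5 was gained among endothelial markers (40.9), and MAP2 and SYT1 among neuronal markers (65.3).

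In LS174T the mesenchymal transition genes had a high count of losses. Of 30 measured, 19 had a peak in parental cells, 16 in LvM1 and 16 in LvM2, and 4 were lost against 0.765 in random lists (percentile 99.7). These were ITGB6, an integrin subunit with 40 reads in parental cells, LOX, a collagen cross-linking enzyme with 32, MMP7, a matrix protease with 32, and PLAUR with 38, at the lower end of the gene rather than the end gained in SW480. SPARC was gained (51.1). With -log10 q of at least 5 a single loss was left, at percentile 62.9. The percentile was 87.9 with LvM2 alone and 97.2 with ends far from other genes. None of these 4 lost genes passed the scaled calling limit, nor did the 7 gained in SW480.

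Hepatocyte markers had a high count of losses in LS174T. AMBP, APOH, FGA and CYP2C8, genes of plasma proteins and a liver cytochrome, were 4 lost of 30 against 1.22 in random lists (percentile 98.2). At least as many were lost in 3.06% of random lists. The percentile was 91.4 with LvM1 alone, 95.2 with windows of 250 bp, 96.6 with lists of equal length and 97.4 with ends far from other genes. FGG, HP, ORM1 and SERPINC1, also plasma proteins, were 4 gained (95.3, not high), although the whole ORM1 region was present in parental cells. The percentile of these gains was high with lists of equal length (97.7) and unmatched random lists (98.6). It was 62.0 with LvM1 alone and 58.5 with ends far from other genes. Only FGA, with 49 reads in parental cells, passed the scaled calling limit. Neuronal markers had GAD2, SLC17A6 and TUBB3 lost, 3 of 20 (98.0), with ELAVL4 and NEFL gained (83.7). Random lists had at least as many losses in 3.45% of draws. With windows of 250 bp none was lost, and the percentile of losses was 66.1 with -log10 q of at least 5, 96.1 with lists of equal length and 72.3 with ends far from other genes.

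Enterocyte absorption genes were gained in 3 of 26 in LS174T (percentile 88.7), namely SI, the sugar-digesting enzyme sucrase-isomaltase, the chloride transporter SLC26A3 and VIPR1, whose whole region was present before. REG4 and TFF2 were gained among goblet and secretory genes (77.4), SYP and TAC1 among enteroendocrine genes (79.3), with NEUROD1 lost. EPHB2 was gained and PROM1 lost among Wnt targets and stem cell genes, and 0 of 30 epithelial transcription factors and 0 of 30 junction genes were gained or lost in both derivatives. HOX genes had HOXC8, HOXC11, HOXC13 and HOXD11 gained (94.3) and HOXA7, HOXB2 and HOXD1 lost (92.8), but the whole regions of HOXC11 and HOXA7 were present in every stage and that of HOXD1 also in LvM2. With LvM1 alone, 11 HOX genes were gained against 3.69 in random lists (99.96) and 5 were lost (97.46). With LvM2 alone, 5 were gained (88.9) and 6 lost (91.9). Among hypoxia genes MXI1 was gained, with 124 and 113 reads in LvM1 and LvM2, while KDM3A and LOX were lost (96.4). The whole regions of EPHB2, NEUROD1, TGFBR1 and ESAM were likewise present in every stage, and that of KDM3A also in LvM1.

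The cytokine gene IL6 was gained in LS174T with 56 and 59 reads, 1 of 24 inflammatory genes (percentile 55.4), and 0 of these were lost. PMEPA1 and TGFBR1 were gained in TGF-beta signalling (91.1), UGT1A1, a conjugating enzyme, was gained and AKR1C3 lost among detoxification genes, and G6PC1 was gained among metabolic genes (55.2). IFIT1, an interferon-induced gene, was lost with 55 reads in parental cells, and IFI44L was gained (54.9). CHMP2A and RPL7A were gained among broadly used genes (96.4), and BRDT and SYCP1 among cancer-testis genes (63.8). COL6A3 and DES were gained among fibroblast markers (85.4), CD2 and CORO1A among immune markers (78.5), and ESAM and LYVE1 were lost among endothelial ones (87.2). YAP and TEAD targets and the CoREST and HMG20B complex had 0 gained and 0 lost. Of 92 counts over both lines 6 were high, where random lists gave 1.98 on average. The random lists were not matched for neighbours that share a peak or for genes held by several lists. With ends far from other genes, which are fewer, none of the 6 stayed high.

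**Figure D2:**
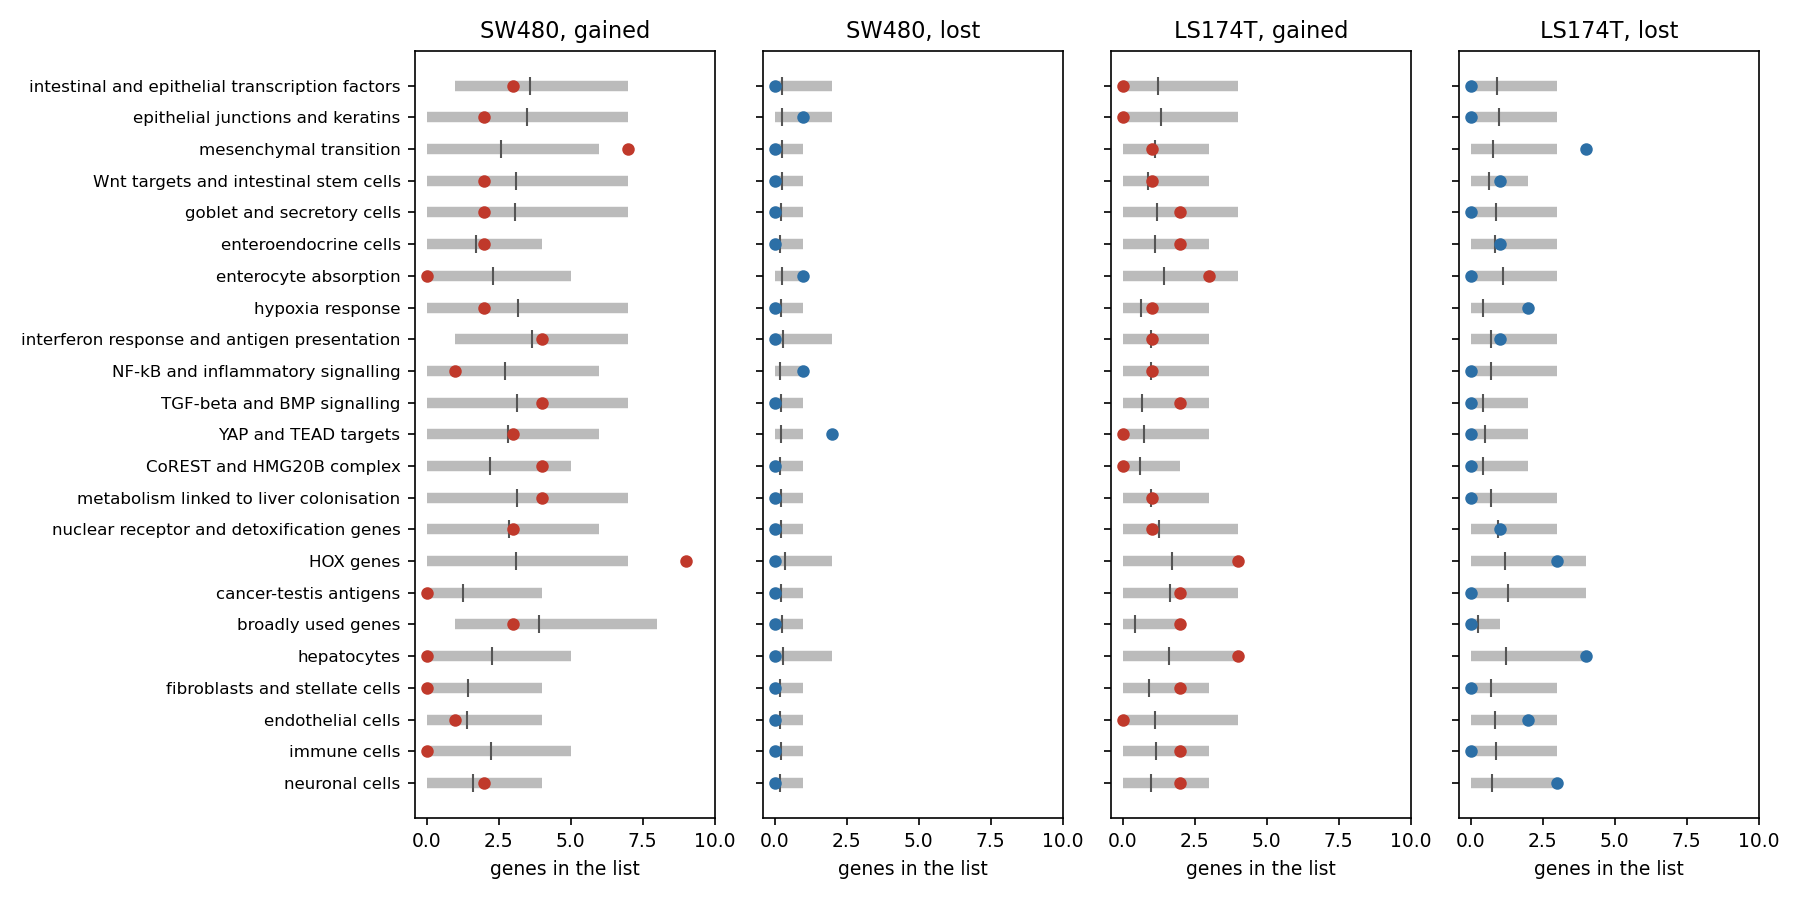
Genes gained (red points) and lost (blue points) per gene list in each line. The horizontal axis is the number of genes, grey bars span the central 95% of 10000 random matched lists and ticks mark their mean. In SW480 the gained counts of mesenchymal transition (7) and HOX genes (9) lie beyond the bars, as do the lost counts of YAP and TEAD targets (2) in SW480 and mesenchymal transition (4) in LS174T. The lost counts of hepatocytes (4) and neuronal cells (3) in LS174T, also called high, lie at the upper ends of their bars.

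The same genes were gained in both lines more often than in independent lists. SNX33, a sorting nexin, CHMP2A, a subunit of the membrane-remodelling ESCRT complex, SYP, a synaptic vesicle protein, and BAG3, a co-chaperone, were among 54 such genes, against 25.8 for independent lists (interval 17 to 35). ANKRD2, TUBB6, SMUG1, a DNA repair glycosylase, TMC8, NANOS1 and RAD21L1 completed the 10 of best rank. SYP had 16 and 20 reads in SW480 LvM1 and LvM2, and 95 and 73 in LS174T. SNX33 had 35 and 35 reads in SW480 and 117 and 110 in LS174T, where its whole region was present in parental cells. WDR18, KIF3C, SERPINF1, ABCA4, POU4F1 and PPIAP40 were lost in both lines, 6 genes against 0.816 for independent lists (interval 0 to 3). Their parental peaks had 9 to 14 reads in SW480 and 27 to 55 in LS174T, against medians of 14 and 38 over all parental peaks. By the scaled limit 0 genes remained lost in both lines. Whether gene ends near the calling limit account for these losses was not tested.

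The strongest peaks of a line were mostly shared between its stages. Of 4086 strongest peaks in SW480, 5.53% (4.85 to 6.28%) of those of LvM1 and 5.26% (4.60 to 5.99%) of those of LvM2 had no peak in parental cells. In the other direction, 1.66% (1.29 to 2.11%) of the parental ones were missing from LvM1 and 3.43% (2.89 to 4.03%) from LvM2. Of 50821 strongest peaks in LS174T, 11.1% (10.8 to 11.4%) of those of LvM1 and 9.98% (9.72 to 10.2%) of those of LvM2 had no peak in parental cells. Of its parental ones, 6.50% (6.29 to 6.72%) were missing from LvM1 and 10.1% (9.82 to 10.3%) from LvM2. The lists searched were of unequal length, with the parental list the shortest in both lines, and a shorter list can lack more peaks without any change of chromatin. With the best 10% of peaks the SW480 shares for parental against LvM2 came close, at 1.29% and 1.41%.

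**Figure D3:**
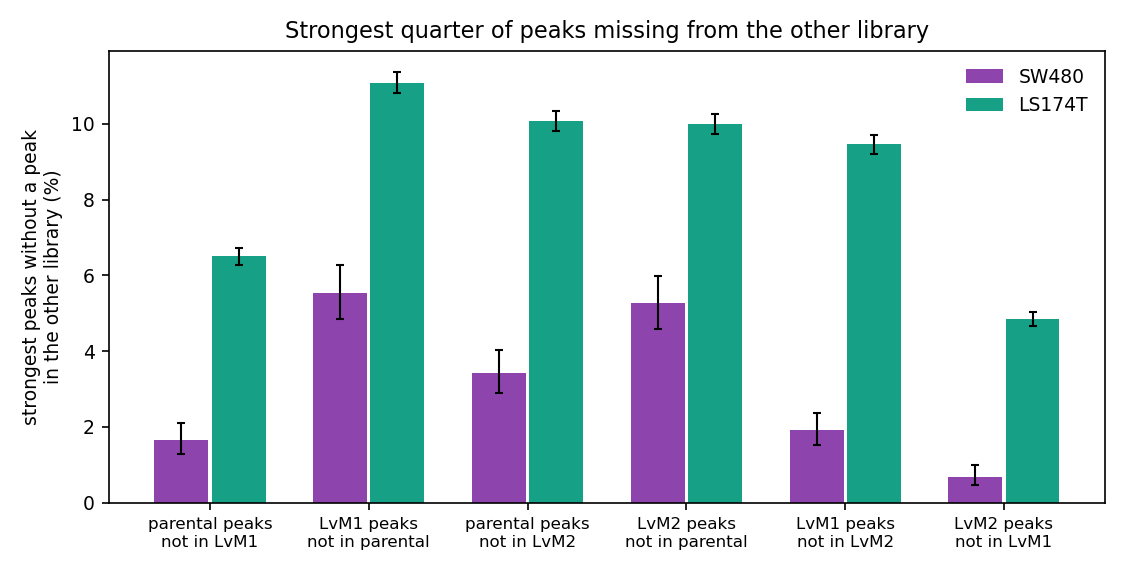
Share of the strongest peaks of 1 library (%, vertical axis) that had no peak in another library of the same line, for each ordered pair of stages in SW480 and LS174T. Bars are single values over 4086 (SW480) or 50821 (LS174T) peaks, and error bars are exact 95% intervals for counting error. In SW480 the LvM peaks missing from parental cells (5.53 and 5.26%) exceed the parental peaks missing from LvM1 and LvM2 (1.66 and 3.43%), but the parental list searched was the shortest.

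Stages of a line shared more of their peak bases than the lines did. The Jaccard index in bases was 0.332 to 0.446 among the 3 SW480 pairs and 0.346 to 0.361 among the 3 LS174T pairs, against 0.0474 to 0.0870 for the 9 pairs between lines, where unequal list lengths cap the index. With all 6 lists cut to the shortest it was 0.409 to 0.531, 0.615 to 0.662 and 0.209 to 0.275. The peak of highest -log10 q was the same region in all 6 lists, on chromosome 3, from 93470358 to 93470791 in SW480 parental cells. It had 1393 reads there and 6871 in LS174T parental cells, against medians of 14 and 38 over all peaks. Regions of extreme signal were not filtered out, so this peak need not reflect shared open chromatin. Between 66.0% and 78.5% of the regions of an SW480 library had a peak in an LS174T library.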

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

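For 4 gene groups the number of genes with a peak at an end changed in opposite directions in the lines, and the difference between the lines was not tested. Of these, only mesenchymal transition had a high count of gained or lost genes in either line. Mesenchymal transition had 8 more such genes in LvM1 and 10 more in LvM2 than in parental cells of SW480, while LS174T had a change of -3 in each. Hypoxia response genes rose by 4 in both SW480 derivatives and changed by -2 and -3 in LS174T. Interferon response and antigen presentation genes rose by 6 and 4 in SW480 and changed by -3 and -2 in LS174T. Genes of the CoREST and HMG20B complex rose by 5 and 4 in SW480 and changed by -1 in each LS174T derivative. All genes together had more peaks in both derivatives of SW480, so a rise there is the general direction. In LS174T all genes together had more in LvM1 (14495 against 13762) and fewer in LvM2 (13582).

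Single genes also went opposite ways, again without a test of the difference. The number for independent lists was not computed for opposite changes, so the counts below do not show an excess. In all, SW480 gained 2008 genes and lost 168, and LS174T gained 720 and lost 518. Among 27 genes gained in SW480 and lost in LS174T were PLAUR, PARD3, a cell polarity protein, F2R, a thrombin receptor, NPAS2, a clock gene, and HOXD1. Counting whole regions left 22 of them, and PLAUR, KLHL12, PIF1 and HOXD1 are among the genes whose region was present before and after passage in at least 1 line. Another 8 were lost in SW480 and gained in LS174T: STAT5A, a cytokine signalling factor, GPT, an aminotransferase, CNRIP1, CORO2B, EXTL1, GUCY1A2, LRMDA and OR2AE1. Counting whole regions left 5.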

How the results depend on the processing

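Why values moved is stated only where the construction of the alternative shows it, and otherwise the cause was not tested. Of the values of the main comparisons under alternatives, 50 stayed within their limits and 86 moved, and for single genes and lists the numbers were 1002 and 478. Part of the 1002 was fixed in advance. By construction every named gene keeps its call with either LvM library alone, and every lost one with lists of equal length. The 1002 is thus no measure of how stable the calls were. The balance of gained and lost turned in SW480 regions with lists of equal length and by the scaled limit, and in SW480 genes by the scaled limit. It turned in LS174T regions with either LvM library alone and by the scaled limit, and in LS174T genes with -log10 q of at least 5, lists of equal length and LvM2 alone. The scaled limit leaves few regions, set by their pileups and a single ratio per library, so its turns do not bear on the full lists. The main rule is not even for gained and lost regions, while the rule with a single LvM library is. The alternatives that scaled pileups, counted whole regions or left out ends near other genes were chosen after seeing the data. Windows at every transcript start and the motif counts were not run, since the gene table gives no transcript starts and no sequence was used. Depth limits SW480 most, where a peak rested on a median of 14 to 15 reads.

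With -log10 q of at least 5, SW480 lost 584 regions and 85 genes, and LS174T gained 10721 regions, lost 17993 and gained 358 genes. The genes gained in both lines were then 33 against 8.86 for independent lists. With lists of equal length, SW480 gained 2676 regions and 1063 genes and lost 523 genes. Genes gained in both lines were 24 against 7.73, and lost 13 against 3.22.

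A smaller requirement raises counts by construction. With LvM2 alone, SW480 gained 10655 regions, lost 4228 and lost 565 genes, and LS174T gained 99390 regions and 1219 genes and lost 76966 regions and 1399 genes. With LvM1 alone, SW480 gained 15882 regions and 3210 genes and lost 303 genes, and LS174T gained 110217 regions and 1562 genes and lost 829 genes. Genes gained in both lines were 104 against 72.5 with LvM2 alone and 251 against 142 with LvM1 alone, and lost ones 45 against 12.1 and 14 against 2.45.

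Windows of 250 bp left 468 gained genes in LS174T. Ends far from other genes, fewer by construction, left 761 gained and 95 lost genes in SW480, 476 gained in LS174T, and 17 gained in both lines. By the scaled limit 10 regions and 3 genes remained gained in SW480 and 233 regions and 19 genes lost. In LS174T 1749 regions and 90 genes remained gained and 866 regions and 41 genes lost, and in both lines 0 and 0, where 0 and 0.0279 fit independent lists, so these counts decide nothing. In simulated data this limit kept 35 of 200 truly absent regions, and all 12 with a mean pileup of at least 40. Simulated losses were not tried.

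The number of gene lists with a high percentile, 2 gained and 1 lost in SW480 and 0 gained and 3 lost in LS174T, moved as follows. Gained lists in SW480 were 1 with lists of equal length, LvM1 alone or ends far from other genes, and 0 with windows of 250 bp. Lost lists in SW480 were 0 with -log10 q of at least 5 or ends far from other genes, and 2 with lists of equal length. Gained lists in LS174T were 1 with -log10 q of at least 5, lists of equal length, LvM1 alone or unmatched random lists. Lost lists in LS174T were 1 with -log10 q of at least 5, lists of equal length or windows of 250 bp, and 0 with ends far from other genes.

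Among the best 10% of peaks, 0.428% and 1.29% of the SW480 parental ones were missing from LvM1 and LvM2, and 1.59% and 1.41% of the LvM1 and LvM2 ones from parental cells. The same shares in LS174T were 0.694%, 2.26%, 2.99% and 2.62%. Ranked by fold enrichment they were 2.84%, 4.67%, 10.5% and 8.93% in SW480 and 7.62%, 10.4%, 11.6% and 11.4% in LS174T. LvM peaks were missing from parental cells more often than the reverse in each pair of stages, except LS174T LvM2 in the main setting.

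The Jaccard index with -log10 q of at least 5 was 0.349 to 0.520 in SW480, 0.409 to 0.431 in LS174T and 0.0718 to 0.140 between lines. With all 6 lists cut to the shortest it was 0.409 to 0.531, 0.615 to 0.662 and 0.209 to 0.275. Pairs within a line stayed above pairs between lines in every setting.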

Other observations

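Interferon and antigen presentation genes that had a peak in every SW480 stage rose less in LvM1 than other gene ends of similar pileup, and in LvM2 their median stayed inside the central 95% of random lists. The median log2 change relative to those was -0.40 in LvM1, with 14 of 15 genes below 0 (percentile 0.02 of random lists), and -0.23 in LvM2, with 12 of 15 below (4.36). IRF7, a transcription factor of the interferon response, was at -0.55 and -0.60, and TAP1, a peptide transporter that shares its region with PSMB9, at -0.43 and -0.39. HLA-E was at 0.11 in LvM1 and -0.59 in LvM2. The 7 junction and keratin genes compared had a median of -0.05 in LvM1 (percentile 37.5) and -0.46 in LvM2 (0.72). The tight junction genes CLDN3 and CLDN4 were at -0.78 and -0.56 in LvM2 and EPCAM at 0.46.

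In LS174T, enterocyte absorption genes had a median of 0.14 in LvM1 and 0.16 in LvM2 (percentiles 98.1 and 98.3). Only 10 genes were compared, with 3 and 4 of them below 0. CYP3A4, a drug-metabolising enzyme, was at 0.40 and 0.56, ANPEP, a brush border peptidase, at 0.37 and 0.44, and SLC26A2, a sulfate transporter, at -0.28 and -0.04. Hypoxia genes had 0.12 in LvM1 (99.5) and 0.00 in LvM2 (50.7), with 8 and 10 of 20 genes below 0, ADM at 0.41 and 0.43, CA9 at 0.35 and 0.46 and PFKFB3 at -0.38 and -0.38. Mesenchymal transition genes kept in LS174T had 0.05 and 0.13 (72.4 and 95.3), opposite in sign to the losses of that group. The 9 kept in SW480 had -0.0014 and 0.23 (47.5 and 92.8). The 5 HOX genes kept in SW480 had -0.12 and -0.26 (26.6 and 15.4), opposite in sign to the gains of that group. HMG20B was at 0.48 in LvM1 and 0.87 in LvM2 of SW480, higher than 88.9% and 97.9% of 7130 gene ends. In LS174T HMG20B was at 0.12 and -0.21, higher than 74.4% and 14.5% of 11946. Of 70 list medians computed, 5 were at or beyond percentile 2.5 or 97.5, where chance gives 3.5.

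All 8 tests of explanations below were chosen after the results they concern were seen. SW480 had more gained than lost regions, 5362 against 2766. Deeper LvM libraries are argued against by the genome background, which in LvM2 was 0.871 times that of parental cells. Weaker enrichment of reads in peaks of the parental library stays open, as draws at scaled pileups with no other change would miss 54.8% as many regions in parental cells as were gained, against 90.9% for unchanged regions in simulated data. An earlier test of it by the scaled limit, passed by 0.186% of gained regions, was set aside because in simulated data that limit kept no more than 35 of 200 truly absent regions, though all 12 with a mean pileup of at least 40. More accessible sites after passage through the liver also stay open, because a better library or more open chromatin could give pileups over background at least 1.52 times those of parental cells in kept regions.

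Kept regions of SW480 on chromosome 13 had lower ratios of LvM to parental pileup than kept regions of the whole genome. The median log2 difference was -0.35 in LvM1 and -0.50 in LvM2, relative to genome-wide median ratios of 1.53 and 1.35. The chromosome was picked as the most extreme of 22 autosomes, with chromosome 21 next at -0.18 and -0.19, and in LS174T it was at 0.03 and 0.05. The kind of region found there is argued against by median differences of -0.31 and -0.45 from regions matched on pileup and gene-end position. A base composition bias of gene-poor chromosomes stays open, as chromosome 4 was at 0.19 and 0.15 but chromosome 18 at -0.10 and 0.01. So do fewer copies of the whole chromosome, since the 4 of 4 bins of 10 Mb that lay below the genome median in both LvM libraries were only 4 of 11, covering 20 to 50 and 110 to 120 Mb.

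Genes gained in both lines exceeded the number for independent lists by 2.09 times. That 1 region is counted at the ends of several neighbouring genes is argued against by a ratio of 2.51 with ends over 5 kb from other genes. Gene ends near the calling limit in both lines could still account for it, as SW480 gained genes were also 2.10 times as frequent as for independent lists among LS174T genes with a peak in LvM1 alone. Among those with a peak in LvM2 alone the ratio was 0.881, which the explanation does not foresee. A shared response to passage was not tested apart from this.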
